A study of Mus musculus with 15 samples.

How the data were processed

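RNA was sequenced from cultured mouse small cell lung cancer lines, which per the labels' protocols were extracted from tissue and grown in medium with a low serum share. Per the labels, the genotypes were Rb1-/-:Trp53-/-:MYC (RPM) and the same with STAT3-/- added (RPMS), and the lines came from the lung or the liver. Libraries were made from total RNA with a stranded kit, per the labels' protocols. Per the labels' processing fields, HISAT2, StringTie and the genome build GRCm38 belong to the authors' processing. Their roles, their versions, the annotation and the strand setting of the counting are not stated. The authors deposited 2 tables of read counts per gene, which hold whole numbers without normalization and unequal totals per library. The first table (set 1) holds 7 libraries and the second (set 2) holds 8, and all 15 samples were matched to a column by their labels.

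Set 1 has 53689 named gene records and set 2 has 53618, of which 53520 names are shared. Set 2 also has 1832 records without a name, with 0.0569% to 0.0800% of a library's counts, which were left out. Repeated symbols (19 and 108 records) were kept apart, and 26 and 27 records carry a date in place of a symbol. Gene positions and classes came from a GENCODE annotation of GRCm38, matched by symbol for 96.8% of the set 1 records and 96.9% of the set 2 records. Total counts ran from 25344949 to 31345631 in set 1 and from 9453715 to 18451248 in set 2, so that 3 counts equal 0.0957 to 0.118 CPM (counts scaled to library size) in set 1 and 0.163 to 0.317 CPM in set 2. No pair of libraries was a copy of another: over the 49 pairs within a set, the mean chi-square per gene between libraries ranged from 48.1 to 819.

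Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's default expression filter, libraries were scaled with TMM factors, and groups were compared with the two-sided quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. CPM values use the TMM-scaled library sizes. Standard errors (SE) of log2 fold changes were taken from the F statistic. RPMS lung was compared with RPM lung within set 1 (3 against 4 libraries), and RPMS liver with RPMS lung within set 2 (4 against 4). Lines CMV_228, CMV_231 and CMV_252 are in both sets, and their set 2 libraries were compared with their set 1 libraries. RPMS liver and RPM lung lie in different tables, so that contrast used all 15 libraries in limma-voom (limma 3.58.1) with the set as a term and the line as a random block, with a consensus correlation of 0.396. For the pairing of the shared lines, the deviations of same-numbered libraries from their set means correlated at r = 0.429 (line CMV_228), 0.553 (CMV_231) and 0.530 (CMV_252) over 11125 genes, and each set 2 library correlated best with its own number. The line numbers were therefore taken to pair the libraries as the same cell lines. For line CMV_252 of set 2 this identity stays open, as given below.

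The 25 gene lists, the tests and the rule for named genes were fixed before the data were examined. The lists cover the type I interferon response, cytosolic DNA and RNA sensing, interferons and their receptors, MHC class I, MHC class II, STAT3 and IL-6 family signalling, NF-kB and inflammatory cytokines, neuroendocrine genes, subtype and lineage regulators of small cell lung cancer, the Notch pathway, YAP/TAZ targets, tuft cells, mesenchymal genes, epithelial genes, the cell cycle, DNA methylation and chromatin silencing, hypoxia and glycolysis, cholesterol biosynthesis, extracellular matrix and proteases, hepatocytes, fibroblasts and stellate cells, leukocytes, endothelium, alveolar and airway epithelium, and sex-linked genes. Lists with at least 3 tested members were tested with camera on log2 CPM (prior count 2, preset correlation 0.01), with adjustment over the lists of a comparison. The rule named the 4 genes of the genotypes (Stat3, Rb1, Trp53, Myc), 12 genes of STING signalling and tumour subtype, the 8 higher and 8 lower genes with the largest fold change among adequately expressed genes past the threshold without overlap of the groups, and up to 3 members of each list. Some genes that the rule names are not reported here. A fold against a group with 0 counts is given as a bound against a floor of 3 counts per library, and where a group has 1 to 3 counts a 95% counting interval is given. Floors and intervals cover counting error only.

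Alternatives were DESeq2 1.42.0, limma-voom, relative log expression and upper-quartile factors, no filter, a minimum of 10 counts, a robust fit, a threshold of 0.01, a test against a log2 fold change of 1, a joint fit of both tables, leaving out each library, and for lists an estimated correlation and fry. For the set comparison the line number as a block was an alternative. Other splits of the libraries were counted, all or at most 100. The tests were checked on simulated counts with 200 changed genes per comparison, 100 at 4-fold and 100 at 16-fold. edgeR recovered 28 of the 4-fold and 82 of the 16-fold genes for RPMS lung against RPM lung (17173 genes), with 2 false calls. It recovered 50 and 89 for liver against lung (14108 genes), with 8 false calls, and 9 and 64 for the set comparison (15881 genes), with 8 false calls. limma-voom recovered 20 and 70 for liver against RPM lung (18265 genes), with 7 false calls. In these simulations 46.1%, 30.9% and 39.6% of the DESeq2 calls were false for the first, second and set comparisons. Recovery and false shares depend on how many genes change. The real first and set comparisons had 5403 and 2608 calls, so the simulated values need not hold there. Changed genes were drawn only from the better expressed genes. Simulated libraries varied independently for each gene, without deviations shared across a whole library or between libraries of a line. The simulated recovery therefore need not hold for liver against lung either.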

Results

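The data are RNA-seq read counts from 15 libraries of mouse small cell lung cancer lines. Per the labels, RPM lines lack Rb1 and Trp53 and carry MYC, and RPMS lines lack Stat3 as well. Set 1 holds 4 RPM lung lines (CMV_426, CMV_427, CMV_428 and CMV_429; 25344949 to 28104574 counts) and 3 RPMS lung lines (CMV_228, CMV_231 and CMV_252; 30178564 to 31345631 counts). Set 2 holds 4 RPMS lung lines (CMV_228, CMV_231, CMV_232 and CMV_252; 15278868 to 18399357 counts) and 4 RPMS liver lines (CMV_273, CMV_341, CMV_343 and CMV_344; 9453715 to 18451248 counts), of which line CMV_344 had the fewest. Line CMV_344 nevertheless had the most genes detected, 30341 against 21658 to 24549 in the other set 2 libraries. Lines are named by the part of the sample title that both sets share. Values are TMM-scaled CPM with SD over the libraries of a group, and positions refer to GRCm38. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named.

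RPMS lung lines were compared with RPM lung lines to ask how gene expression differs when Stat3 is deleted. Stat3 itself (chromosome 11, 100885098 to 100939540) stood at 186 ± 21.1 CPM in RPM (SD, n = 4) and 14.4 ± 5.84 CPM in RPMS (n = 3), a log2 fold change of -3.69 (SE 0.35, edgeR adjusted p = 0.00176). Many macrophage-type leukocyte, interferon, antigen presentation and mesenchymal genes were lower in RPMS lines, and many neuroendocrine and cell cycle genes were higher. Of 25 gene lists 15 passed camera's threshold at its preset correlation, and 1, NF-kB and inflammatory cytokines, held with an estimated correlation. Tmem173, which encodes the DNA-sensing adaptor STING (chromosome 18, 35733679 to 35740554), fell from 43.3 ± 19.97 to 1.93 ± 1.18 CPM, a log2 fold change of -4.49 (SE 0.67, edgeR adjusted p = 0.00467). Summed leukocyte genes were at 3244 to 15630 CPM in the RPM libraries and at 2.89 to 125 CPM in the RPMS libraries. For the genes of this comparison, an effect of Stat3 loss therefore cannot be told apart from a difference in the cells that make up the cultures.

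The edgeR test placed 5403 of 17654 genes past the threshold, 2639 higher and 2764 lower in RPMS lung. The 2 groups did not overlap in 7593 genes (43%), where chance gives 5.71%, and 5249 of these passed. Among the 8 higher genes with the largest change were Elavl3, Eef1a2, Myb, Crmp1, Klhl13, Adcy1 and Scg3, at 171 to 483 CPM in RPMS and at most 1.54 CPM in RPM on average. Elavl3, a neuronal RNA-binding protein (chromosome 9, 22015005 to 22052023), rose by a log2 fold change of 9.44 (SE 1.49, edgeR adjusted p = 0.00552), and the haematopoietic transcription factor gene Myb rose by 8.53 (SE 0.67, adjusted p = 0.00136). The 8 lower genes with the largest change had 0 counts in all 3 RPMS libraries. Cybb (chromosome X, 9435252 to 9487771), a subunit of the phagocyte NADPH oxidase, was at least 7894-fold lower, and Myof (chromosome 19, 37899036 to 38043577), a membrane repair protein, at least 5231-fold lower. C1qc and C1qb of complement were at least 4321-fold and 4232-fold lower, Ifitm3 at least 3730-fold, Adgre1 at least 3132-fold, Ptprc at least 3083-fold and Msr1 at least 2870-fold. The call of Klhl13 was lost without RPMS line CMV_228 (edgeR adjusted p = 0.0519), and that of Scg3 without line CMV_228 (0.0599) or line CMV_231 (0.0545). The count of genes was 2896 without RPMS line CMV_228 and 3103 without line CMV_231.

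**Figure D1:**
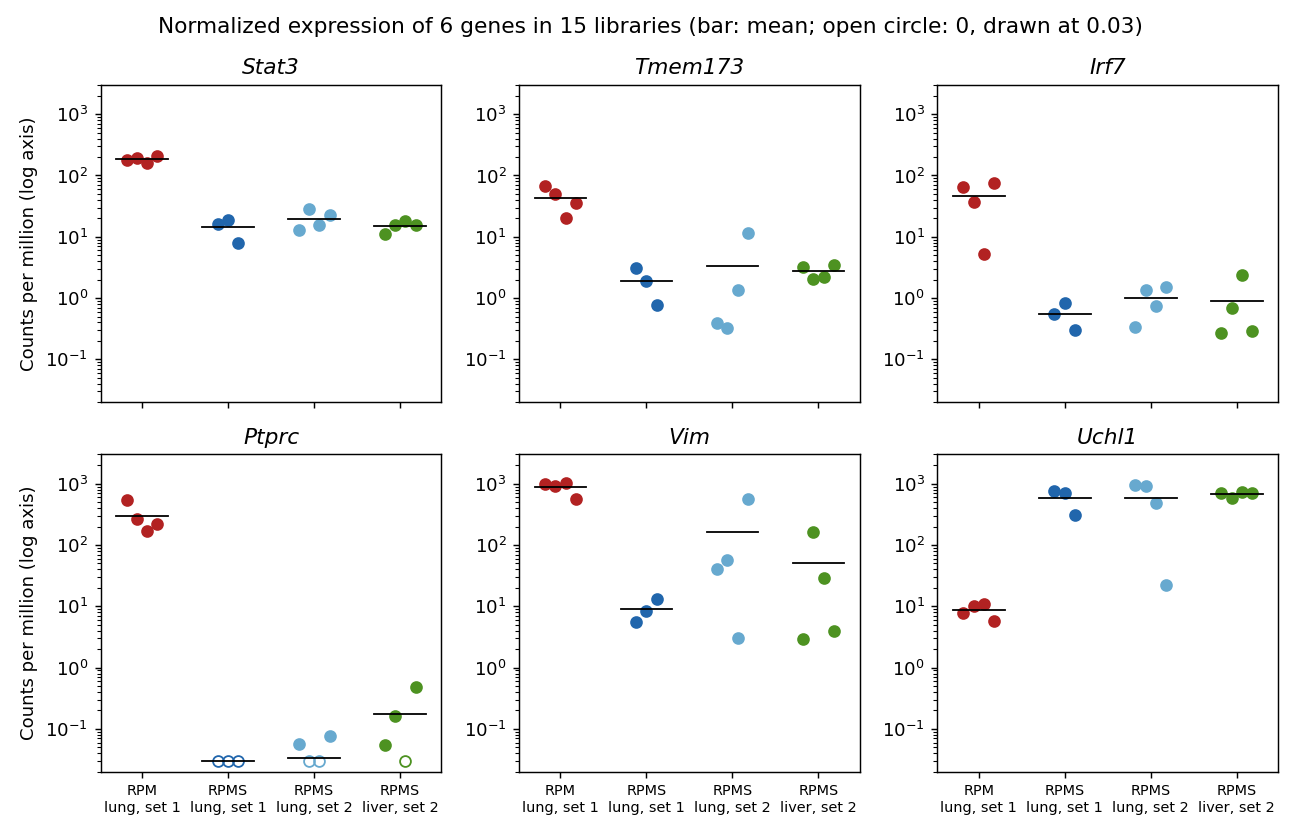
Normalized CPM (log axis) of 6 genes in each of the 15 libraries, by group; bars are group means and open circles are libraries with 0 counts. Stat3, Tmem173, Irf7 and Ptprc lie higher in all 4 RPM libraries than in all 3 RPMS libraries of set 1, as does Vim, and Uchl1 lies lower, and Vim is at 556 in set 2 line CMV_252.

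Of the other genes of the genotypes, Rb1 was at 48.0 ± 8.70 CPM in RPM and 91.9 ± 60.7 CPM in RPMS (edgeR adjusted p = 0.241), and Trp53 was at 4.24 ± 1.89 and 2.39 ± 3.30 CPM (adjusted p = 0.571). Rb1 was at least 38.7 CPM in every RPM library, so its level per gene does not show the deletion that the labels give. Without RPMS line CMV_252 both passed, Rb1 with a log2 fold change of 1.39 (adjusted p = 0.00623) and Trp53 with -3.12 (adjusted p = 0.0140). Myc fell from 20.8 ± 10.2 to 1.82 ± 1.54 CPM (log2 fold change -3.52, SE 0.76, adjusted p = 0.0146), a call that was lost without RPMS line CMV_231 (adjusted p = 0.0603). The same RPMS lung lines had 40.4 ± 29.6 CPM of Myc in set 2, so its level differed between the tables. The labels do not say whether transcripts of the engineered MYC allele are counted as Myc.

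Genes of the type I interferon response were lower in RPMS lung: 32 of 40 tested members fell and 8 did not pass, or 36 lower when adjusted over the list alone. Irf7, a transcription factor of interferon induction, fell from 45.6 ± 31.2 to 0.560 ± 0.261 CPM (log2 fold change -6.34, SE 1.06, edgeR adjusted p = 0.00664), Ifit3 from 35.6 to 0.228 CPM and Samd9l from 162 to 0.339 CPM. In cytosolic DNA and RNA sensing 14 of 22 members fell, and 14 adjusted over the list alone. They include the double-stranded RNA receptor gene Tlr3 (17.7 to 0.227 CPM), Mavs (61.1 to 10.6 CPM), Samhd1 (221 to 63.5 CPM) and Mb21d1, which encodes cGAS (22.3 ± 8.35 to 3.46 ± 1.53 CPM, adjusted p = 0.00726). Tbk1 fell from 77.4 to 46.9 CPM (adjusted p = 0.0214), a call lost without RPM line CMV_427 (0.0551), RPMS line CMV_228 (0.0857) or RPMS line CMV_231 (0.0663). Irf3 was at 25.4 and 16.9 CPM (adjusted p = 0.159), and Ifnb1 had 0 counts in all 7 libraries. The Mb21d1 call was lost in the joint fit of both tables (limma adjusted p = 0.0698). Camera gave adjusted p = 2.41e-13 for the interferon response and 3.67e-06 for sensing. With an estimated correlation the adjusted p was 0.232 and 0.226, so neither list held. In the same libraries, summed leukocyte genes were at 3244 to 15630 CPM in RPM and at most 125 CPM in RPMS.

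Interferon receptor, antigen presentation and inflammatory genes were lower in RPMS lung as well. Of the tested genes of interferons and their receptors 7 of 8 fell, also 7 adjusted over the list alone, among them Il10rb (130 to 5.39 CPM), Ifngr2 (112 to 19.6 CPM) and Jak1 (224 to 75.2 CPM). In MHC class I antigen presentation 16 of 21 fell, or 18 adjusted over the list alone, with the MHC transactivator Nlrc5 at 56.6 and 0.114 CPM, Tapbp at 220 and 11.8 CPM and Erap1 at 108 and 12.6 CPM. For MHC class II 4 of 7 fell, or 5 adjusted over the list alone, with Ifi30 at 127 and 11.7 CPM and H2-DMb1 at least 198-fold lower. Ctss had 86169 counts in RPM and 2 in RPMS, with a 95% counting interval of 3.22e-06 to 9.61e-05 for the RPMS to RPM ratio. In STAT3 and IL-6 family signalling 15 of 29 fell, or 17 adjusted over the list alone. Osmr, the oncostatin M receptor, was at least 237-fold lower, Icam1 stood at 90.8 and 0.183 CPM and Junb at 74.7 and 12.2 CPM. In NF-kB and inflammatory cytokines 19 of 21 fell, or 20 adjusted over the list alone, with Nfkb2 at 51.3 and 1.35 CPM, Csf1 at 46.2 and 0.861 CPM and Tnf at least 60.2-fold lower. Camera gave adjusted p = 4.01e-05 for the receptors, 6.13e-08 for MHC class I, 0.000491 for MHC class II, 2.82e-06 for STAT3 and IL-6 signalling and 1.32e-10 for NF-kB. With an estimated correlation the adjusted p was 0.0815, 0.226, 0.160, 0.0815 and 0.0194, so of these only the NF-kB list held. Summed leukocyte genes again were at 3244 to 15630 CPM in RPM and 2.89 to 125 CPM in RPMS.

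Neuroendocrine genes were higher in RPMS lung: 22 of 28 rose and 6 did not pass, or 26 higher when adjusted over the list alone. The neural adhesion molecule gene Ncam1 rose from 7.30 ± 2.26 to 250 ± 35.6 CPM (log2 fold change 5.10, SE 0.31, edgeR adjusted p = 0.000916), Uchl1 from 8.66 to 587 CPM and the neuronal tubulin gene Tubb3 from 1.96 to 242 CPM. Camera gave adjusted p = 2.93e-12, and with an estimated correlation the adjusted p was 0.188. Neurod1 was at least 36.9-fold higher, with 0 counts in RPM. Pou2f3 had 4 counts over the RPM libraries and 0 in RPMS. Among the subtype and lineage regulators 7 of 18 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.192), with Hes6 at 20.7 and 186 CPM and Sox9 at 26.5 and 0.811 CPM. Nfib rose from 122 ± 81.6 to 618 ± 143 CPM (adjusted p = 0.0259), a call lost without RPM line CMV_427 (0.0598) and without RPMS lines CMV_228 (0.0702), CMV_231 (0.0563) or CMV_252 (0.0548) in turn. Summed neuroendocrine genes were at 75.8 to 184 CPM in RPM libraries and 2230 to 6809 CPM in RPMS libraries, the lowest in line CMV_252, while summed leukocyte genes were at 3244 to 15630 and 2.89 to 125 CPM.

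In the Notch pathway 6 of 17 genes rose and 5 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.794). Dll3, an inhibitory ligand, rose from 0.0588 to 96.9 CPM and Dtx1 from 0.184 to 74.2 CPM, while the receptor gene Notch2 fell from 193 to 16.3 CPM. The Dll3 call was lost with limma-voom (adjusted p = 0.105) and in the joint fit (0.0550). Rest, a repressor of neuronal genes, was at 63.9 ± 6.97 CPM in RPM and 3.94 ± 6.64 CPM in RPMS (log2 fold change -4.02, edgeR adjusted p = 0.125), and without RPMS line CMV_252 it passed at -9.15 (adjusted p = 0.00415). It passed with DESeq2 (0.0243), limma-voom (0.0112) and the joint fit (0.000846) as well. Yap1 was at 18.4 ± 8.76 and 5.50 ± 7.55 CPM (adjusted p = 0.255) and passed without line CMV_252 at -4.01 (adjusted p = 0.0128). Of the YAP/TAZ targets 7 of 21 fell and 1 rose (9 and 1 adjusted over the list alone), with the receptor kinase gene Axl at least 2760-fold lower and Lats2 at 40.3 and 0.477 CPM. The mesenchymal list had 14 of 21 lower and 1 higher (14 and 2 adjusted over the list alone), with vimentin (Vim) at 876 ± 210 and 9.02 ± 3.67 CPM, Itga5 at 83.1 and 0.213 CPM and Sparc at least 2178-fold lower. Of the extracellular matrix and protease genes 12 of 21 fell (16 adjusted over the list alone), with Timp2 at 419 and 35.0 CPM and Plau at 104 and 1.71 CPM. Camera gave adjusted p = 4.01e-05 for YAP/TAZ targets, 1.48e-06 for mesenchymal genes and 0.000120 for the matrix. With an estimated correlation the adjusted p was 0.232, 0.0815 and 0.0815, so none of these 3 lists held. None of 15 epithelial genes passed with edgeR (0 adjusted over the list alone, camera adjusted p = 0.962), and Elf3, with the smallest p, was at 3.85 and 12.1 CPM (adjusted p = 0.0744; 0.0208 with DESeq2, 0.0435 with limma-voom and 0.0496 without RPM line CMV_428). Beside these groups, the leukocyte sums were those given for the interferon genes. Fibroblast sums were 263 and 734 CPM in RPM lines CMV_428 and CMV_429, 216 and 36.9 CPM in CMV_426 and CMV_427 and 51.7 to 65.4 CPM in RPMS lines. Alveolar sums were 1462 and 1823 CPM in CMV_428 and CMV_429, 197 and 264 CPM in CMV_426 and CMV_427 and 157 to 177 CPM in RPMS lines. Sparc was at 346 and 312 CPM in CMV_428 and CMV_429 and at 94.1 and 93.0 CPM in CMV_426 and CMV_427.

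Cell cycle and cholesterol synthesis genes were higher in RPMS lung. In the cell cycle list 16 of 29 rose (20 adjusted over the list alone), including Ccne2 (38.7 to 133 CPM), Rrm2 (35.7 to 197 CPM) and the replication licensing gene Mcm2 (188 to 501 CPM). For cholesterol biosynthesis 10 of 21 rose, and 10 adjusted over the list alone, including the squalene epoxidase gene Sqle (115 to 265 CPM) and Cyp51 (111 to 283 CPM). Camera gave adjusted p = 2.85e-06 and 0.000282, and with an estimated correlation the adjusted p was 0.396 and 0.232. In DNA methylation and chromatin silencing 7 of 23 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.134), with Hdac2 at 111 and 287 CPM, Tet1 at 0.831 and 56.8 CPM and Ezh1 at 43.5 and 11.7 CPM. In hypoxia and glycolysis 2 of 19 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.488), with P4ha1 at 96.4 and 33.0 CPM. The 2 risers, Tpi1 and Gapdh, have near-identical copies in the genome and are uncertain, and both lost their calls in most fits that left out a library. Gapdh was lost without any RPM line and without RPMS line CMV_228 or CMV_231 (adjusted p = 0.0774 to 0.137). Tpi1 was lost without RPM lines CMV_426, CMV_427 or CMV_428 or RPMS lines CMV_228 or CMV_231 (0.0537 to 0.131). Summed leukocyte genes were again 3244 to 15630 CPM in RPM and 2.89 to 125 CPM in RPMS.

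Markers of other cell types differed between the groups. Of the leukocyte genes 13 of 15 tested fell (15 adjusted over the list alone), including the macrophage receptor gene Csf1r (844 ± 558 to 0.0608 ± 0.0604 CPM) and Laptm5 (406 to 0.134 CPM). Camera gave adjusted p = 5.85e-14, and with an estimated correlation the adjusted p was 0.129. In the tuft cell list 7 of 9 fell and 1 rose, also when adjusted over the list alone, with camera adjusted p = 0.000131 and adjusted p = 0.143 with an estimated correlation. Its lower members include Vav1 (at least 1144-fold) and Alox5ap (68.8 to 0.417 CPM), which leukocytes are known to express. Of the fibroblast genes 6 of 11 fell and 1 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.192), with Thy1 at 0.0579 and 5.05 CPM, Acta2 at least 49.3-fold lower and Mgp at least 386-fold lower. The Mgp call was lost with limma-voom (adjusted p = 0.0547). Of the endothelial genes 1 of 7 fell (0 adjusted over the list alone, camera adjusted p = 0.334): Flt1, at 44.0 and 0.383 CPM, a call lost without RPM line CMV_427 (0.0668) or CMV_428 (0.0654) or RPMS line CMV_228 (0.0836) or CMV_231 (0.0819). For alveolar and airway epithelium 1 of 12 fell, Napsa, at 18.8 and 0.114 CPM (1 adjusted over the list alone, camera adjusted p = 0.149). Without RPM line CMV_427 the fibroblast (0.0202) and alveolar lists (0.0280) passed camera. Of 4 hepatocyte genes tested Trf fell and Tat rose (1 and 1 adjusted over the list alone, camera adjusted p = 0.962, upward while the median was -0.86). Trf lost its call without RPMS line CMV_228 (adjusted p = 0.0601) and Tat without any of the RPM lines or without RPMS line CMV_252 (0.0693 to 0.0834). None of the 5 sex-linked genes passed with edgeR (0 adjusted over the list alone, camera adjusted p = 0.808), and Eif2s3y was at 42.4 ± 49.7 and 7.45 ± 12.9 CPM.

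**Figure D2:**
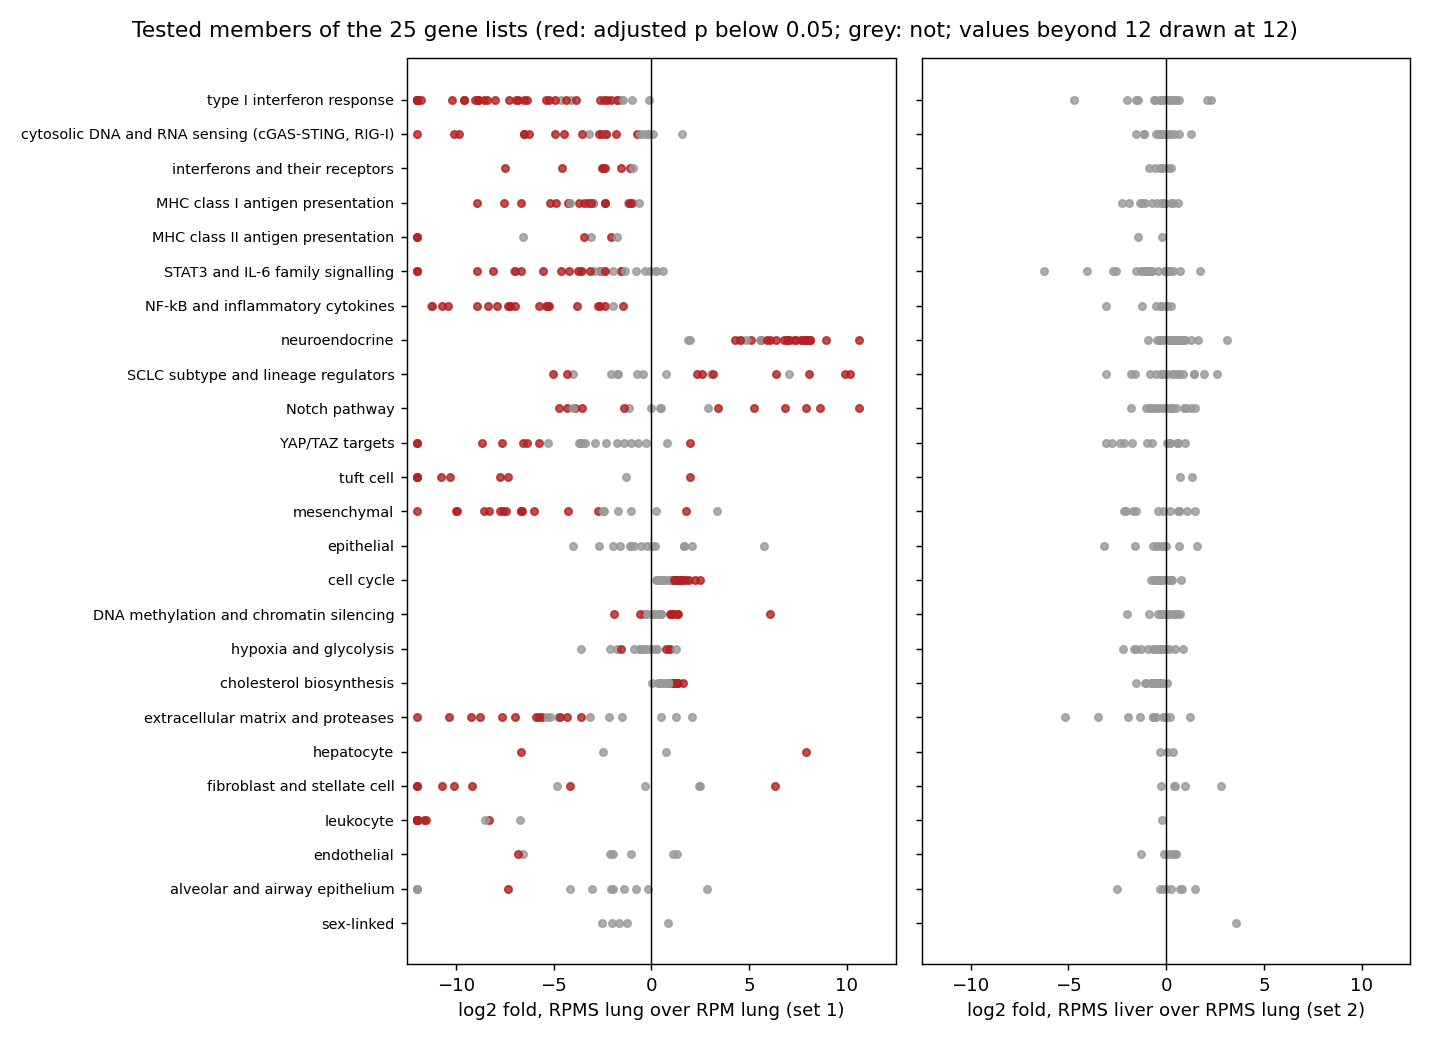
Log2 fold change of each tested member of the 25 lists in RPMS lung over RPM lung (left) and RPMS liver over RPMS lung (right); red points passed edgeR's threshold and grey points did not. On the left, interferon, NF-kB and leukocyte members lie below 0 where red and neuroendocrine members above 0; on the right no point is red.

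RPMS liver lines were compared with RPMS lung lines to ask whether lines from liver metastases differ from those of the lung. No gene passed with edgeR: 0 of 14441, with 650 at an unadjusted p under 0.05 where chance gives 722, and a lowest adjusted p of 0.0857. Stat3 was at 19.8 ± 7.14 CPM in lung lines (n = 4) and 15.02 ± 2.77 CPM in liver lines (n = 4), and Tmem173 at 3.39 ± 5.40 and 2.73 ± 0.668 CPM, with adjusted p of 0.946 and 0.988. Line CMV_252 had 11.5 CPM of Tmem173 and the other lung lines 0.326 to 1.37 CPM, and without it the log2 fold change turned from -0.30 to 1.97 (adjusted p = 0.835). The genes with the smallest p, chosen after their values were seen, were Akap6 (chromosome 12, 52699383 to 53155599) and Matn4. Akap6, which encodes a kinase anchoring protein, was at 0.151 ± 0.170 CPM in lung and 61.8 ± 33.6 CPM in liver lines, with each liver line (18.4 to 91.0 CPM) above each lung line. Matn4, a matrix protein gene, was at 29.1 ± 15.7 CPM in lung and 0.447 ± 0.300 CPM in liver lines, with no overlap. In all, 369 genes (2.56%) had no overlap between the groups, where chance gives 2.86%. limma-voom called 0 genes and DESeq2 called 52 (37 higher, 15 lower in liver). Without a filter edgeR called Akap6 (adjusted p = 0.00401) and Matn4 (0.00629), and the joint limma fit called Matn4 and Mybpc1 (both 0.0438), the latter also chosen after its value was seen.

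Among the lists, 4 passed camera at its preset correlation, and with an estimated correlation each had adjusted p = 0.865, so none held. Cholesterol biosynthesis (20 tested members) lay lower in liver lines, with camera adjusted p = 2.98e-08, and Fdft1 was at 182 ± 42.3 CPM in lung and 106 ± 15.5 CPM in liver lines. Neuroendocrine genes (28 members) lay higher with adjusted p = 0.00200, with the granule protein gene Scg2 at 3.19 ± 2.51 and 27.7 ± 14.2 CPM. Hypoxia and glycolysis (18 members) lay lower at 0.0248, with Egln3 at 12.6 and 3.98 CPM, and MHC class I (17 members) lay lower at 0.0405, with the chaperone gene Calr at 1408 ± 1211 and 553 ± 179 CPM. Calr moved from a log2 fold change of -1.35 to -0.54 without line CMV_252 (3200 CPM). Without set 2 line CMV_252 the neuroendocrine list was at adjusted p = 0.744, hypoxia at 0.250 and MHC class I at 0.270, while mesenchymal genes passed upward (0.000968), cell cycle genes downward (0.000968) and fibroblast genes upward (0.0266). In liver line CMV_341 the fibroblast sum was 230.3 CPM and the mesenchymal sum 859 CPM, against 21.4 to 61.7 CPM and 343.1 to 481 CPM in the other liver lines. NF-kB (0.0460) and matrix genes (0.0266) also passed upward without line CMV_252, against their direction with all lines. Cell cycle genes passed as well without line CMV_273 (0.00190), CMV_341 (0.0107) or CMV_343 (0.0332), but not without line CMV_344. In that liver line the cell cycle sum was 4145 CPM, against 7010 to 8641 CPM in the other liver lines. Mesenchymal (0.0197) and fibroblast genes (0.000337) passed without line CMV_273, and interferon genes passed downward without line CMV_343 (0.00780). Leaving out any of lines CMV_231, CMV_232, CMV_273 or CMV_341 also ended the MHC class I call (adjusted p = 0.136, 0.245, 0.479 and 0.292), leaving out line CMV_232 or CMV_344 that of hypoxia (0.245 and 0.107), and leaving out line CMV_343 that of the neuroendocrine list (0.0508). No member of any list passed with edgeR, and adjusted over the list alone 1 gene did, Ifi30 of MHC class II, at 36.3 ± 17.6 CPM in lung and 13.3 ± 3.40 CPM in liver lines.

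The other lists did not pass camera in liver against lung. Adjusted p was 0.592 for the interferon response, 0.596 for sensing, 0.698 for interferon receptors, 0.297 for STAT3 and IL-6 signalling, 0.825 for NF-kB, 0.297 for subtype regulators, 0.478 for Notch, 0.825 for YAP/TAZ, 0.478 for mesenchymal, 0.825 for epithelial and 0.0574 for cell cycle genes. It was 0.698 for chromatin silencing, 0.698 for the matrix, 0.723 for hepatocyte, 0.473 for fibroblast, 0.478 for endothelial and 0.698 for alveolar genes. Camera and the list's median differed in sign for Notch, YAP/TAZ (both upward, medians -0.02 and -0.33) and hepatocyte genes (downward, median 0.03). MHC class II, tuft cell, leukocyte and sex-linked genes had fewer than 3 tested members and no list test. Members with the smallest p in their lists include the interferon-induced Bst2, at 29.3 ± 51.3 CPM in lung and 1.14 ± 0.888 CPM in liver lines, Jak2 at 25.9 and 41.7 CPM, Sox2 at 89.3 and 30.1 CPM, Zeb1 at 98.4 and 150 CPM and Dnmt3a at 136 and 225 CPM. Bst2 was at 106 CPM in line CMV_252 and 1.30 to 8.01 CPM in the other lung lines, and its log2 fold change moved from -4.70 to -1.70 without that line. Yap1 was at 55.3 ± 105 and 6.57 ± 6.57 CPM, with a log2 fold change that turned from -3.07 to 1.14 without line CMV_252, and Neurod1 at 6.47 and 24.9 CPM. The liver markers Alb, Ttr and Apoa1 stayed at or below 0.434 CPM in all 8 libraries, and summed leukocyte genes at 4.58 to 27.4 CPM.

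Line CMV_252 of set 2 differed from the other RPMS lung lines in these genes. It had 212 CPM of Yap1 where the other 3 lung lines had 2.33 to 3.72 CPM. The vesicle protein gene Chga was at 1.61 CPM and Insm1 at 9.99 CPM, against at least 244 and 629 CPM in the other 3. Its MHC class I sum was 5624 CPM against 1230 to 1917 CPM. Calr gave 3200 CPM of it (607 to 1082 CPM in the other 3) and B2m 162 CPM. Its mesenchymal sum was 1437 CPM against 290 to 352 CPM.

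**Figure D3:**
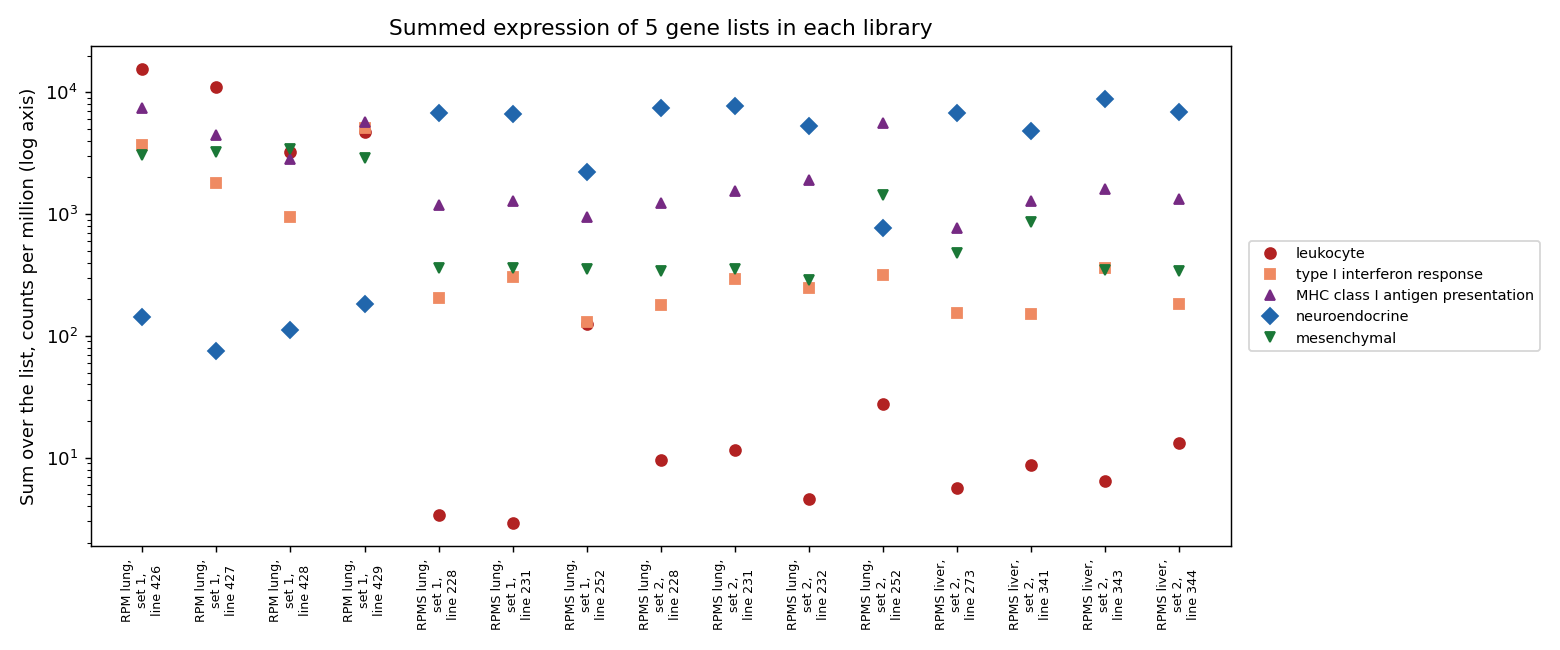
Sum of the normalized CPM (log axis) over the genes of 5 lists in each of the 15 libraries. Neuroendocrine sums are at most 184 in the 4 RPM libraries and 776 in set 2 line CMV_252, and leukocyte sums are at least 3244 in the RPM libraries and at most 125 elsewhere.

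Set 2 libraries of lines CMV_228, CMV_231 and CMV_252 were compared with set 1 libraries of the same lines to measure how the 2 tables differ. Of 16328 genes edgeR placed 2608 past the threshold, of which 2182 were lower in set 2 and the rest higher. Pseudogenes made up 75.1% of the annotated lower genes, 3.53% of the higher genes and 2.46% of the genes not past. The glycolysis gene Gapdh, which has many processed copies, was at 40.7 to 130 CPM across set 1 and 1093 to 3226 CPM across set 2. Myc was higher in set 2, at 1.91 ± 1.70 and 40.4 ± 29.6 CPM (log2 fold change 4.40, SE 0.92, adjusted p = 0.0207), a call lost without line CMV_228 of set 1 (0.0673), line CMV_231 of set 1 (0.0912) or line CMV_231 of set 2 (0.0617). Of the other named genes Trp53 was at 2.55 and 15.8 CPM (adjusted p = 0.202; log2 fold change 5.01 with adjusted p = 0.00736 without line CMV_252 of set 1) and Stat3 at 14.6 and 20.9 CPM. Tmem173 was at 1.95 and 3.95 CPM (adjusted p = 0.712) and was lower in set 2 without line CMV_252 in both sets (log2 fold change -2.80, adjusted p = 0.0180). The count was 1546 and 1624 without lines CMV_228 and CMV_231 of set 1, and 1668 and 1570 without those lines of set 2. Without line CMV_252 in both sets it was 4758. With 3 pairs of lines a block on the line gave 2562 genes, of which 2223 were shared with the unblocked test.

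RPMS liver lines and RPM lung lines were compared across the tables, through the lines in both. These groups differ in both genotype and site, so a call cannot be assigned to the liver. Summed leukocyte genes were at 3244 to 15630 CPM in RPM lung and 5.7 to 13.3 CPM in liver lines. Stat3 was lower in RPMS liver, with a log2 fold change of -4.12 (SE 0.43, limma adjusted p = 5.27e-05). Rest (-7.28, adjusted p = 0.00812) and Tbk1 (-1.05, adjusted p = 0.00956) were lower and Nfib higher (2.79, adjusted p = 0.0125), and Neurod1, with 0 counts in RPM lung and 0.584 to 64.1 CPM in liver lines, was higher (adjusted p = 0.0260). Irf7 was lower at -6.27 (adjusted p = 0.0289). Its call was lost without any set 1 RPMS line, set 2 lung lines CMV_231 or CMV_252 or liver lines CMV_273 or CMV_344 (0.0511 to 0.0641). That of Neurod1 was lost without line CMV_252 of set 1 (0.0666). With edgeR and a set term, Rest (0.117) did not pass. Tmem173 had a log2 fold change of -3.33 (limma adjusted p = 0.0775) and passed with edgeR and a set term (0.0290). It passed without RPM line CMV_428 (0.0466) and without set 2 lines CMV_228 (0.0481) or CMV_231 (0.0493). Myc passed at -3.69 (adjusted p = 0.00367) and Trp53 did not at -1.37 (0.254; 0.00577 without line CMV_252 of set 1), and both lay higher in liver lines when the set term was left out, by 0.86 and 2.52. In all, limma placed 5118 of 18568 genes past the threshold, 2801 higher and 2317 lower. Without the set term 9755 passed and the median fold change of all genes moved by 0.11 (log2).

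The fold changes of the 2 main comparisons were related across 13827 genes, with the RPMS lung lines on opposite sides of both. Pearson's r was 0.314 and the covariance 0.481, across genes, which are not independent replicates. Unchanged groups sharing the lines gave r = -0.223 (95% of draws from -0.525 to 0.0741) and covariance -0.133, a difference in covariance of 0.614. With the lung lines split between the comparisons, r was -0.0721, 0.0148 and 0.540 with line CMV_228, CMV_231 or CMV_252 in the liver comparison, and without set 2 line CMV_252 it was -0.0764, so the relation rested on the set 2 library of line CMV_252. Without line CMV_252 of set 1 r was 0.340. No gene passed in both comparisons, since edgeR called 0 genes in liver against lung.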

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

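The tests of leukocytes in the RPM cultures, of leukocytes as carriers of the interferon genes, of reads shared between copies and of 5 other cell types in line CMV_252 were chosen only after the results were seen. Checks covered each named gene and 3 library measures (total counts, genes detected, mitochondrial share) within a group of 4 libraries. In 21 of 168 checks 1 library lay far from the other 3, in a named gene or in its total counts. Chance would give about 1 in 20 checks, or 8.4, for independent checks, but these share the same libraries. The values below are the gap of the library that lay apart to the nearest other library divided by the range of the group, on the log2 scale for genes.

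RPM line CMV_426 had the highest level of some neuronal genes among the RPM lines, while the summed neuroendocrine genes were highest in line CMV_429 (184 CPM, and 142 CPM in CMV_426). The gap was 0.844 for Elavl3, 1 for Eef1a2 and for Scg3, which had 0 counts in the other 3 lines, and 0.933 for Crmp1. The levels in line CMV_426 were low, at 2.43, 3.21, 3.80 and 3.61 CPM of Elavl3, Eef1a2, Scg3 and Crmp1. Line CMV_426 was also highest in Tet1 (0.849), at 2.08 CPM, and in the receptor gene Il10rb (0.924). RPM line CMV_428 was lowest in the interferon-induced Ifitm3 (0.835), at 110 CPM against 395 to 509 CPM.

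In set 2, line CMV_252 was lowest of the RPMS lung lines in Neurod1 (0.926) and Sox2 (0.844), both regulators of lineage. It was highest in Yap1 (0.908), Nlrc3 (0.868), Ifnar2 (0.862), the protease gene Adamts1 (0.909) and the endothelial receptor gene Kdr (0.901). Line CMV_232 was highest in the replication gene Mcm5 (0.927), at 712 CPM against 220 to 240 CPM. Among liver lines, CMV_343 was highest in Rb1 (0.867) and lowest in Ifi30 (0.841), CMV_273 was lowest in Irf3 (0.907) and Xist (0.921), and CMV_344 was lowest in Dnmt3a (0.862) and in total counts (0.936).

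Leukocyte genes were far higher in RPM than in RPMS lung lines, and interferon, sensing and antigen presentation genes were higher too. Of 20 measured leukocyte genes 14 were higher in every RPM library than in every RPMS library, and 11 of 14 macrophage genes exceeded 100 CPM in each RPM library, which restates the pattern, so leukocytes in the RPM cultures cannot be told apart from tumour cells that express these genes. The number of RPM libraries with leukocyte sums at or below those of the RPMS libraries was 0. The sums did not rank alike. Line CMV_429 had the highest interferon sum (5131 CPM) with 4710 CPM of leukocyte genes, and line CMV_427 had 1817 and 11050 CPM. Set 2 line CMV_252 had an MHC class I sum of 5624 CPM with 27.4 CPM of leukocyte genes. Of that MHC class I sum 3200 CPM came from the chaperone gene Calr alone. Whether such leukocytes carry the interferon, sensing and antigen presentation transcripts therefore cannot be told apart from an effect of Stat3 loss in the tumour cells, which stays open and untested.

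Genes lower in set 2 than in set 1 of the same lines were mostly pseudogenes (75.1%), so reads shared between near-identical copies and counted in only 1 table are a candidate cause. At their set 1 level, 98.08% of the lower genes would have at least 10 counts in each of the compared set 2 libraries. The same held for 93.07% of the genes not past. Genes had to pass an expression filter to be tested, so a low share was hardly possible. This test therefore cannot decide whether the lower depth of set 2 plays a part. Overlap with a gene on the opposite strand was found for 40.92% of the lower coding genes and 31.1% of those not past, and since same-strand overlap differed too (42.4% and 7.74%), different strand assignment cannot be told apart from other counting rules. No biological explanation was tested.

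Line CMV_252 of set 2 stood apart from the other RPMS lung lines in neuroendocrine, antigen presentation and mesenchymal genes. Its mitochondrial share of counts was 7.73%, against 3.16% to 4.68% in the other lung lines of set 2. In set 1 the share was 7.07% in line CMV_252 and 2.57% and 3.17% in the other RPMS lines. Whether library quality plays a part was not tested. A label swapped with that of line CMV_232 or a liver line is argued against. The deviation of line CMV_252 of set 2 from lines CMV_228 and CMV_231 correlated with that of line CMV_252 of set 1 at r = 0.531. The highest value for line CMV_232 or a liver line was 0.297. In the pairing of the shared lines, set 2 lines CMV_228 and CMV_231 correlated with line CMV_252 of set 1 at -0.385 and -0.531. This explanation was worded more widely, as a mislabelled library, before the result was seen. The 2 libraries of line CMV_252 still differed, with Xist at 2416 CPM in set 1 and 19.6 CPM in set 2, Neurod1 at 6.71 and 0.0748 CPM, Yap1 at 15.3 and 207 CPM and Nfib at 825 and 250.0 CPM. In set 1 only its neuroendocrine sum stood apart, at 2230 CPM against 6587 and 6809 CPM in the other RPMS lines. The set 1 MHC class I sum was 948 CPM, against 1193 and 1274 CPM. The set 1 mesenchymal sum was 352 CPM, against 360 and 363 CPM. Leukocytes, endothelial cells, fibroblasts, hepatocytes and alveolar cells are argued against as the whole cause, since at most 5.88% of the measured genes of such a list exceeded 10 CPM and the other lung lines, although its leukocyte (27.4 CPM) and fibroblast sums (94.9 CPM) were the highest of the set 2 lung lines. Cells of other types, a line not measured here and a different state of this culture may each remain, as none was tested.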

How the results depend on the processing

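The fits without lines CMV_252 and CMV_344, without line CMV_252 in both sets, and the relation without each library were chosen only after the data were seen. For RPMS lung against RPM lung, relative log expression and upper-quartile factors kept the direction and call of all 93 tested named genes. A threshold of 0.01 gave 2103 genes (906 higher, 1197 lower) and a test against a log2 fold change of 1 gave 2818 (1241 and 1577), both stricter by construction. Leaving out each library gave 2896 to 7076 genes, 1302 to 3530 higher and 1594 to 3546 lower, and 15 to 17 lists. An estimated correlation left 1 list there and 0 in liver against lung. The fry test gave 19 lists there, among them the subtype regulators (adjusted p = 0.00938) and the chromatin silencing, fibroblast and endothelial lists (0.0304 each) that camera did not call, and 0 in liver against lung. For liver against lung DESeq2 called 52 genes (37 higher, 15 lower), and no filter and the joint fit called 2 each (1 higher, 1 lower), while edgeR, limma-voom and each fit without 1 library called 0. Leaving out each library gave 2 to 6 lists, and leaving out lines CMV_252 and CMV_344 gave 2. Without set 2 line CMV_252, NF-kB (adjusted p = 0.046043) and matrix lists (0.026616) passed upward, reversed, and their adjusted p was up to 0.966 without another library. For set 2 against set 1 the higher genes numbered 198 with no filter, 1105 with DESeq2 and 1586 of 4758 without line CMV_252 in both sets. Leaving out each library gave 1546 to 2763 genes, 68 to 481 higher. Without line CMV_252 in both sets Tmem173 reversed to -2.80. The bridged contrast without its set term gave 9755 genes (4699 higher, 5056 lower), and Trp53 (2.52) and Myc (0.86) reversed, as that fit leaves the difference between the tables in the contrast. Across genes, r was -0.0721, 0.0148 and 0.540 with the lines split and ranged from -0.0764 to 0.412 without each library. Unless a construction is named, the cause was not tested. The floor of 3 counts, up to 0.317 CPM in line CMV_344, limits what could be detected.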

Other observations

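Of the tests of splits only that of liver against RPM lung with each line kept together was chosen after the results were seen, and the gene levels in the next 2 paragraphs were chosen after their values were seen. Genes of lung epithelium were present in some RPM cultures. The surfactant genes Sftpc and Sftpb, markers of alveolar type II cells, stood at 147 and 135 CPM in RPM line CMV_428 and at 722 and 348 CPM in line CMV_429, and the club cell gene Cyp2f2 at 320.5 and 343.2 CPM. In lines CMV_426 and CMV_427 these 3 genes were at most 1.57 CPM. Line CMV_429 also had the highest levels of the fibroblast gene Dcn (634 CPM), the keratin gene Krt8 (546 CPM), the MHC class II chain Cd74 (261 CPM) and the acute-phase gene Saa3 (207 CPM). The lysozyme gene Lyz2, a macrophage and alveolar marker, was at 1062 to 8146 CPM in RPM lines, and line CMV_252 had 124 CPM of it in set 1, above the other RPMS lines of that set at most 0.706 CPM.

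Fibroblast genes appeared in 1 liver line, CMV_341, with Dcn at 37.2, Acta2 at 17.2, Col3a1 at 14.2 and Lum at 5.13 CPM, where no other set 2 library exceeded 0.768 CPM in these 4 genes. Sex-linked genes divided the lines within groups. In set 1 Xist was at 1076 to 2416 CPM in lines CMV_426, CMV_427, CMV_228 and CMV_252 and at most 0.361 CPM in the others, which carried the Y-linked Ddx3y (44.7 to 102 CPM). In set 2 Xist was at 240 CPM in line CMV_228, 19.6 CPM in line CMV_252 and 797 to 1423 CPM in liver lines CMV_341, CMV_343 and CMV_344, and Ddx3y was at 30.2 CPM in line CMV_231.

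Other splits of the libraries tested whether chance can be excluded for the counts. For RPMS lung against RPM lung, only the real split of 35 gave as many as 5403 genes, with at most 1 gene in another. Its share lies under the limit of 0.05, so chance is argued against, though 35 splits allow no smaller share. The other splits mix the genotypes, and the test does not separate Stat3 loss from a different make-up of the cultures. As many lists as the real 15 came from 10 of 35 splits, with up to 17 in another. The other splits with as many differed from the real one only by 1 library moved or 1 pair exchanged. They thus keep much of the difference between the genotypes, and splits that divided the RPM libraries evenly gave at most 10 lists. The test therefore cannot decide whether chance gives as many lists, and chance is not excluded. In liver against lung the real count of genes was 0, so all 35 splits had to give as many and the test decides nothing (highest other 1). As many lists as the real 4 came from 26 of 35 splits, with up to 14 in another, so chance cannot be excluded for the number of lists.

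For set 2 against set 1 the 10 splits are too few for a share under 0.05, with 2608 genes in the real split, the only 1 with as many, and 0 in the highest other. Of these splits 4 part all 3 pairs of libraries of a line. For liver against RPM lung the splits that keep the 2 libraries of each line together, as the real split does, number 5 and are too few for a share under 0.05. The real split gave 5118 genes, 4 of the 5 gave as many and the highest other gave 5425. Of 100 splits drawn without that limit 1 gave as many, the highest other gave 4714, and the 5 draws that kept the RPM group together gave at least 2527 while draws that mixed it gave at most 62, which points to the RPM libraries as a structure of the samples.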
